A study of Mus musculus with 13 samples.

How the data were processed

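The material was medial habenula dissected from adult mice that carry the Chat-TRAP transgene. In such mice a GFP-tagged ribosomal protein is made in cholinergic cells, so that polysomes precipitated with anti-GFP beads carry the mRNA those cells were translating (translating ribosome affinity purification, TRAP). Per the labels, 6 immunopurified (IP) libraries came from Chat-TRAP wild-type mice, 6 IP libraries from Gpr151 knockout mice with the same transgene, and 1 library from the unpurified homogenate (input) of wild-type mice. Gene counts per library ran from 28375912 to 64388596, and 3 counts, the limit a count of 0 allows, corresponded to 0.0466 to 0.106 CPM per IP library, counting error only. Each library pooled tissue of 4 mice, or of 3 mice for the libraries numbered 852 and 855. The replicates are therefore separate pools of animals. Per the labels' protocols, RNA was amplified with the Ovation V2 kit before library preparation. Whether counting used strand is not given in the sources used here, so reads of a gene and of an antisense partner were treated as not separable. Most of the deposited tables' names mention saline, and that of the input also saccharin, while the labels give no treatment; groups follow the labels, and whether the input matches the IP animals in treatment is not given in the sources used here.

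The deposited values were raw counts of reads per gene symbol, 1 table per library. Per the submitters' processing notes, STAR 2.3.0e, HTSeq and DESeq2 were used with the mm10 genome build; their settings and the gene annotation are not given in the sources used here. The deposited counts did not share 1 list of genes. The 4 earlier IP libraries (682, 683, 852 and 855) listed 32531 symbols, the 8 later IP libraries (1091 to 1094 and 1099 to 1102) 24454 and the input 37328. The comparison of genotypes used the 23857 symbols shared by all 12 IP libraries, and the comparison with input the 22682 shared by all 13. Summary lines for reads without a gene were left out of library sizes and tests. Of all alignments, 9.44% to 16.6% per IP library lay outside genes and 25.2% to 53.2% were not unique. Reads assigned to more than 1 gene made up 3.98% of alignments in the input, 1.30% to 1.36% in the earlier IP libraries and 0.581% to 0.714% in the later ones. Counts of genes that overlap a neighbour, lie antisense to one or have near-identical copies thus depend on the annotation used.

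Library numbers fall into 3 sets that each hold both genotypes in equal number among the IP libraries (682 and 683, 852 and 855, and the 8 later ones), so the set was a term in the main models of genotype. Replicate numbers were given in accession order and pair no samples. No pair of libraries within a group and set agreed within sampling noise: chi-square per degree of freedom was 23.2 to 547 over the pairs of later libraries.

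Knockout and wild type were compared with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), library sizes were scaled by TMM, and the robust quasi-likelihood test gave two-sided p-values that were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors were derived from the fold change and the F statistic, and 95% intervals from the t distribution on the test's degrees of freedom. Log2 CPM (counts scaled to library size) was computed with a prior count of 2. Lists of genes with 5 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Interaction of genotype with earlier against later libraries was tested in the same kind of model. Single values per library were compared by exact permutation over all splits of 12 libraries into 6 and 6, two-sided, for which the smallest p is 0.00216. Counts of calls were set against those of 100 splits of the 12 libraries into 6 and 6 and, chosen later, of 100 of the 140 splits that halve each library set as the genotypes do, the real split included in both.

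With 1 input library, IP and input were compared mainly by a rule of size. A transcript was called enriched when each of the 6 wild-type IP libraries had at least 2 times the input CPM after adding a pseudocount of 1, and depleted when each had at most the inverse of that ratio. Genes needed 5 CPM in the input or as the mean of the IP libraries. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. As an alternative, edgeR was fitted to the 12 IP libraries and the input with the spread pooled over the IP libraries, which assumes that the lone input varies like them.

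Gene positions came from GENCODE M21 on GRCm38, the assembly named mm10 in the submitters' notes. Of the 23857 symbols, 23788 had a position.

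Named genes followed a rule written before the data were examined: Gpr151, then up to 10 genes per direction past the threshold, or the 5 with the smallest p where fewer than 5 passed, leaving out provisional symbols (Gm followed by a digit, or ending in Rik). Up to 4 members with the smallest p were taken per list, and Chat, Slc18a3, Slc5a7, Chrna3, Chrna5 and Chrnb4 were always given. For IP against input, the 10 most enriched and the 10 most depleted were taken, with up to 4 members per list. The gene lists, the tests and most alternatives were also fixed before the data were examined. The alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, other set terms, parts of the libraries, a covariate for non-neuronal markers, and leaving out each library in turn. Blood cell markers had 1 tested member and were not tested as a list, and no mitochondrially encoded transcript was among the symbols tested.

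The test was run on simulated counts with the means, spread and library sizes of the 12 IP libraries. Among 14165 tested genes it recovered 14.9% of the genes changed 1.5-fold, 73.1% of those changed 2-fold and 95.5% of those changed 3-fold, with 11 false calls. Changes were planted only in genes with a mean of at least 1 CPM, so recovery of lower genes was not measured. Genes varied independently within a library set, so spread shared by many genes was not simulated.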

Results

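Translating mRNA of cholinergic medial habenula neurons was profiled in mice with and without Gpr151, an orphan G protein-coupled receptor that is concentrated in the habenula. The series title names synaptic plasticity and nicotine intake as its subject, and the comparison asks which transcripts on the ribosomes of these neurons differ when the receptor gene is disrupted. There were 6 wild-type IP libraries, 6 knockout IP libraries and 1 wild-type input library. Counts assigned to genes ranged from 28375912 to 58502055 per wild-type IP library and from 32623249 to 64388596 per knockout IP library, and the input held 54701790. The ribosomal RNA precursor Rn45s took 2.25% to 12.6% of the counts of an IP library. Gene counts per library gave no difference between the genotypes (exact permutation p = 0.677, two-sided).

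Gpr151 transcripts were lower in every knockout library. Gpr151 (ENSMUSG00000042816.4) lies on the minus strand of chromosome 18 at 42577881 to 42579652 (GRCm38), in a single exon with its coding sequence at 42578346 to 42579611. Its level was 435 ± 87.5 CPM in wild type and 142 ± 35.4 CPM in knockout (SD, n = 6 each). The log2 fold change was -1.63 with a standard error of 0.17 (95% interval -1.99 to -1.26; edgeR quasi-likelihood test, adjusted p = 0.00331), and the exact permutation p was 0.00216, the smallest these 12 libraries can give. The difference in log2 CPM was -2.09 between libraries 683 and 682, -1.54 between 855 and 852, and -1.54 between the means of the 8 later libraries (exact permutation p = 0.0286, the smallest 4 against 4 can give). Reads were not absent from the knockout: 4785 to 12654 counts per library were still assigned to Gpr151. The counts cover the whole gene, so they do not tell which part of it these reads came from. With the 8 later libraries alone the edgeR log2 fold change was -1.54 and the adjusted p 0.383, against 1.56e-14 to 0.0382 in the other alternatives.

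Of 14317 genes tested, 2 passed the threshold: Gpr151, which fell, and Oxt, which rose. Oxt encodes the precursor of the hypothalamic hormone oxytocin. It had 1 to 3 counts in each wild-type library and 16 to 47 in each knockout library, 11 against 203 in total. After TMM scaling of library sizes the ratio was 17.7 (95% exact interval 9.70 to 36.1, which covers counting error only). Its mean level was 0.0388 ± 0.0102 CPM in wild type and 0.752 ± 0.400 CPM in knockout (SD, n = 6 each), far below that of Gpr151, with edgeR adjusted p = 5.58e-05 and all 6 knockout libraries above all wild-type libraries. The stricter filter of 1 CPM in 6 libraries removed Oxt from the test, and with the 4 earlier libraries alone its log2 fold change was 4.57, against 4.03 with all 12, but its adjusted p was 0.976, against 8.11e-08 to 0.0276 in the other alternatives.

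The genes next in rank did not pass. Among those with higher values in knockout, Pcdhb6, a clustered protocadherin, had a log2 fold change of 1.34 ± 0.22 (SE, edgeR adjusted p = 0.281, higher in 6 of 6 knockout libraries than in any wild-type library), Pnoc, the precursor of nociceptin, 2.23 ± 0.47 (adjusted p = 0.679), Lemd1 1.60 ± 0.34 (adjusted p = 0.679) and Tmc4 2.04 ± 0.47 (adjusted p = 0.795). Among those with lower values, Trim36, a ubiquitin ligase, had -0.63 ± 0.11 (adjusted p = 0.339), Ccdc112 -0.66 ± 0.14, Tagln2 -0.54 ± 0.11 and Ercc2, a helicase of nucleotide excision repair, -0.82 ± 0.17 (adjusted p = 0.679 for these 3). DESeq2 called 12 genes: Gpr151, Oxt, Pcdhb6, Tagln2, Trim36, Gm8615, Ccdc112, Ercc2, Lemd1, Pnoc, Irs4 and Pcdhgb8.

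**Figure D1:**
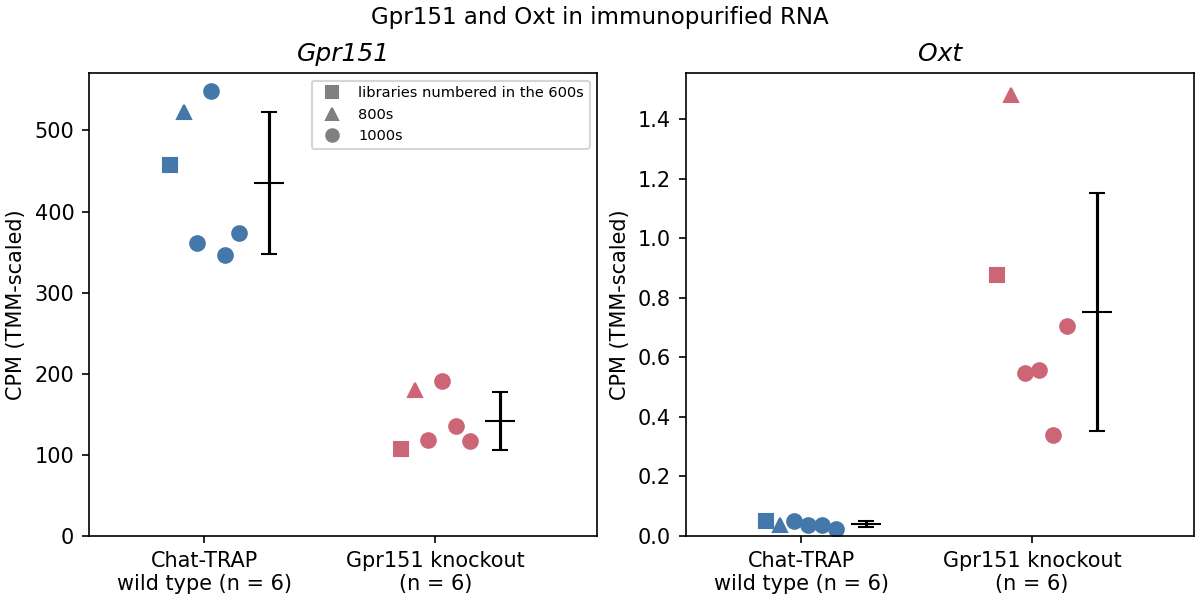
TMM-scaled CPM (vertical axes, linear, from 0) of Gpr151 and Oxt in each of the 6 wild-type and 6 knockout IP libraries, with marker shape for the library set and black bars for mean and SD. Gpr151 lies between 346 and 548 CPM in wild type and between 108 and 191 CPM in knockout, and Oxt is at most 0.050 CPM in wild type and at least 0.34 CPM in knockout.

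Of the 157 tested genes within 10 Mb of Gpr151, edgeR called Gpr151 alone, and DESeq2 called 5, of which 4 were neighbours: Pcdhb6, Trim36, Ccdc112 and Pcdhgb8. A count at an unadjusted p under 0.01 was added after the values were seen. It held 10 of the 156 neighbours, Gpr151 left out (6.41%), with an odds ratio of 12.2 against all other tested genes (Fisher exact p = 4.37e-08, two-sided). These were Trim36, Ccdc112, Pcdhgb8, Pcdhgb5, Myot and Ppp2r2b within 5 Mb, and Pcdhb6, Pcdhb3, Pcdha12 and Tnfaip8 between 5 and 10 Mb. Their directions differed: 6 had higher and 4 lower values in knockout. Of the 53 clustered protocadherins tested among the neighbours, 40 had higher values in knockout, and 5 of the 53 were at p under 0.01. The Fisher test takes genes as independent. Fry, which allows for correlation between genes, gave p = 0.457 for the neighbours and p = 0.0726 for changes in either direction. The share was 8.96% within 5 Mb, 4.49% from 5 to 10 Mb, 4.76% from 10 to 20 Mb, 7.94% from 20 to 30 Mb, 0.990% farther along chromosome 18 and 0.497% on other chromosomes. The 4 genes behind the share from 10 to 20 Mb included the endothelial and mural marker Pdgfrb, and the 5 from 20 to 30 Mb the choroid plexus marker Ttr. Clustered protocadherins share sequence, so their reads can be assigned to the wrong member; without them 5 of 103 neighbours were at p under 0.01. With the later libraries alone the count was 5, and without library 682 or library 683 it was 6. The odds ratio fell to 3.94 without library 1091 (Fisher exact p = 0.000440), 4.88 without library 1100 and 6.67 without library 682 or 683, and rose to 20.3 without library 852 and 19.98 without library 855.

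**Figure D2:**
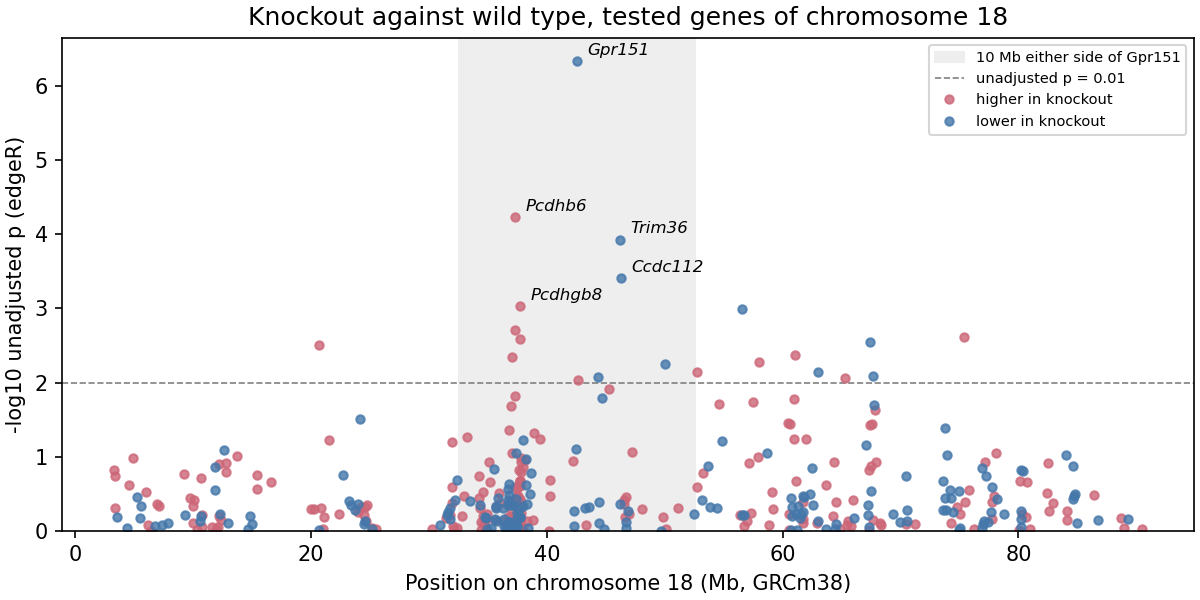
Each point is a tested gene of chromosome 18, by start position (Mb, GRCm38) and -log10 of its unadjusted edgeR p for knockout against wild type, colored by direction. The shaded band spans 10 Mb either side of Gpr151 and the dashed line marks the unadjusted limit of 0.01; Gpr151 stands highest and 10 of its 156 neighbours in the band lie above the line.

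No gene of the cholinergic and nicotinic machinery passed the threshold. Chat, which makes acetylcholine, was at 119 ± 30.6 CPM in wild type and 90.6 ± 20.6 CPM in knockout (SD, n = 6 each). Its log2 fold change was -0.38 (95% interval -0.73 to -0.04, edgeR adjusted p = 0.999). The vesicular acetylcholine transporter Slc18a3 had -0.26 (95% interval -0.81 to 0.29) and the choline transporter Slc5a7 -0.03 (-0.49 to 0.44). Among the nicotinic receptor subunits of the habenula, Chrna3 had -0.01 (-0.37 to 0.34), Chrnb4 -0.10 (-0.50 to 0.31) and Chrna5 -0.27 (-0.75 to 0.22). The values of Slc18a3, Slc5a7, Chrna3 and Chrnb4 turned positive with the non-neuronal score as a covariate (0.06, 0.17, 0.15 and 0.12). Slc18a3 lies within Chat, so the reads of this pair are not fully separable. None of the 10 tested nicotinic subunits passed over all genes or adjusted over the list alone, and their median was -0.02 with a mean of 0.01 (camera adjusted p = 0.928). None of the 10 genes of cholinergic synthesis and transport passed either way (median -0.07, mean 0.002, camera adjusted p = 0.353).

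Genes that act downstream of G protein-coupled receptors or at the synapse likewise gave no call. None of the 36 G protein and cAMP pathway genes, 19 RGS proteins, 16 GABA-B receptor and presynaptic calcium channel genes, 61 synaptic vesicle and release genes or 23 immediate early genes passed over all genes or adjusted over the list alone. Camera adjusted p was 0.269 for the G protein and cAMP genes (median 0.02), 0.236 for RGS proteins (median 0.23), 0.928 for GABA-B and calcium channel genes (median -0.03, mean 0.19), 0.928 for vesicle genes (median 0.06, with the test's direction down) and 0.544 for immediate early genes (median 0.09). The members with the smallest p were Adcy7 (1.10 ± 0.51, SE), Rgs6 (-0.30 ± 0.12), Cacna2d3 (0.97 ± 0.47), Cplx2 (-0.33 ± 0.13) and Arc (-0.29 ± 0.11), on the log2 scale. Substance P neuron genes of the dorsal medial habenula (median -0.04, adjusted p = 0.421), oxidative phosphorylation genes (-0.10, adjusted p = 0.0623), hippocampal markers (0.22, adjusted p = 0.383) and sex-linked transcripts (-0.05, mean 0.06, adjusted p = 0.696) did not pass either.

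Of 11 lists that mark cells other than the purified neurons, camera called 7 higher in knockout with a preset correlation and 0 with an estimated correlation, and neither edgeR nor DESeq2 called a member over all genes. Over all 28 lists, camera with the preset correlation called 14, of which 12 were higher and 2 lower in knockout. With an estimated correlation it called 0 of 28, with 1 list at an unadjusted p under 0.05, and fry likewise called 0. The mean log2 CPM of non-neuronal markers was highest in knockout libraries 1099 (3.49) and 1102 (3.16) and wild-type library 1091 (2.66); without these 3 libraries, a choice made after the data were seen, camera with the preset correlation called 9 lists, and with this score as a covariate it called 1, GABAergic markers. Over all libraries the score was 1.38 ± 0.83 in wild type and 1.95 ± 1.15 in knockout (SD, n = 6 each; exact permutation p = 0.329, adjusted p = 0.470 over 10 measures). Its difference was 0.78 between the means of the later libraries and 0.63 between libraries 855 and 852 but -0.29 between 683 and 682, a pair that was also lower in knockout for the mean log2 CPM of astrocyte (-0.06) and oligodendrocyte markers (-0.44).

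All 8 tested GABAergic neuron markers were above 0 with a median log2 fold change of 1.04 (camera adjusted p = 1.50e-08 with the preset correlation, adjusted p = 0.393 with an estimated correlation), and 6 of them passed when adjusted over the list alone; among them Gad1, which makes GABA, had 1.18 ± 0.38 and the peptide Sst 0.90 ± 0.25 (SE). Per library, the mean log2 CPM of these markers was 1.07 ± 1.03 in wild type and 2.18 ± 0.80 in knockout (SD, n = 6 each; exact permutation p = 0.0693, adjusted p = 0.231 over 10 measures; 0.0857 in the later libraries; 0.0214 when permuted within library sets, a choice made after the data were seen). All 16 astrocyte markers (median 0.86, preset adjusted p = 4.03e-07) and all 16 oligodendrocyte markers (0.75, preset adjusted p = 1.29e-05) were above 0, with Aldoc at 0.78 ± 0.35 and Mobp at 0.64 ± 0.34; both lists had an adjusted p = 0.507 with an estimated correlation. With the preset correlation the same direction was called for oligodendrocyte precursors (0.75), microglia (0.68), GABA and glycine receptors (0.67), thalamic neuron markers (0.60), lateral habenula markers (0.58), neuropeptides and their receptors (0.37), glutamate receptors (0.28), pacemaker and potassium channels (0.18) and heat shock genes (0.14), each with an adjusted p = 0.507 with an estimated correlation. In the neuropeptide list Pnoc passed when adjusted over the list alone, and DESeq2 called it over all genes (adjusted p = 0.0184). Choroid plexus (0.87, adjusted p = 0.119), ependymal (0.30, adjusted p = 0.0908) and endothelial markers (0.29, adjusted p = 0.0885) were not called. The choroid plexus gene Ttr had 3.39 ± 0.94 and passed when adjusted over its list alone. Only 2 of the 6 knockout libraries lay above all wild-type ones for Ttr (4.70 ± 7.16 CPM in knockout and 0.430 ± 0.255 CPM in wild type, SD).

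The lower lists were medial habenula identity (median -0.14, preset adjusted p = 0.00248, adjusted p = 0.507 with an estimated correlation), in which 15 of 18 members were below 0, and cytosolic ribosomal proteins (-0.12, preset adjusted p = 0.0129, adjusted p = 0.746 with an estimated correlation).

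**Figure D3:**
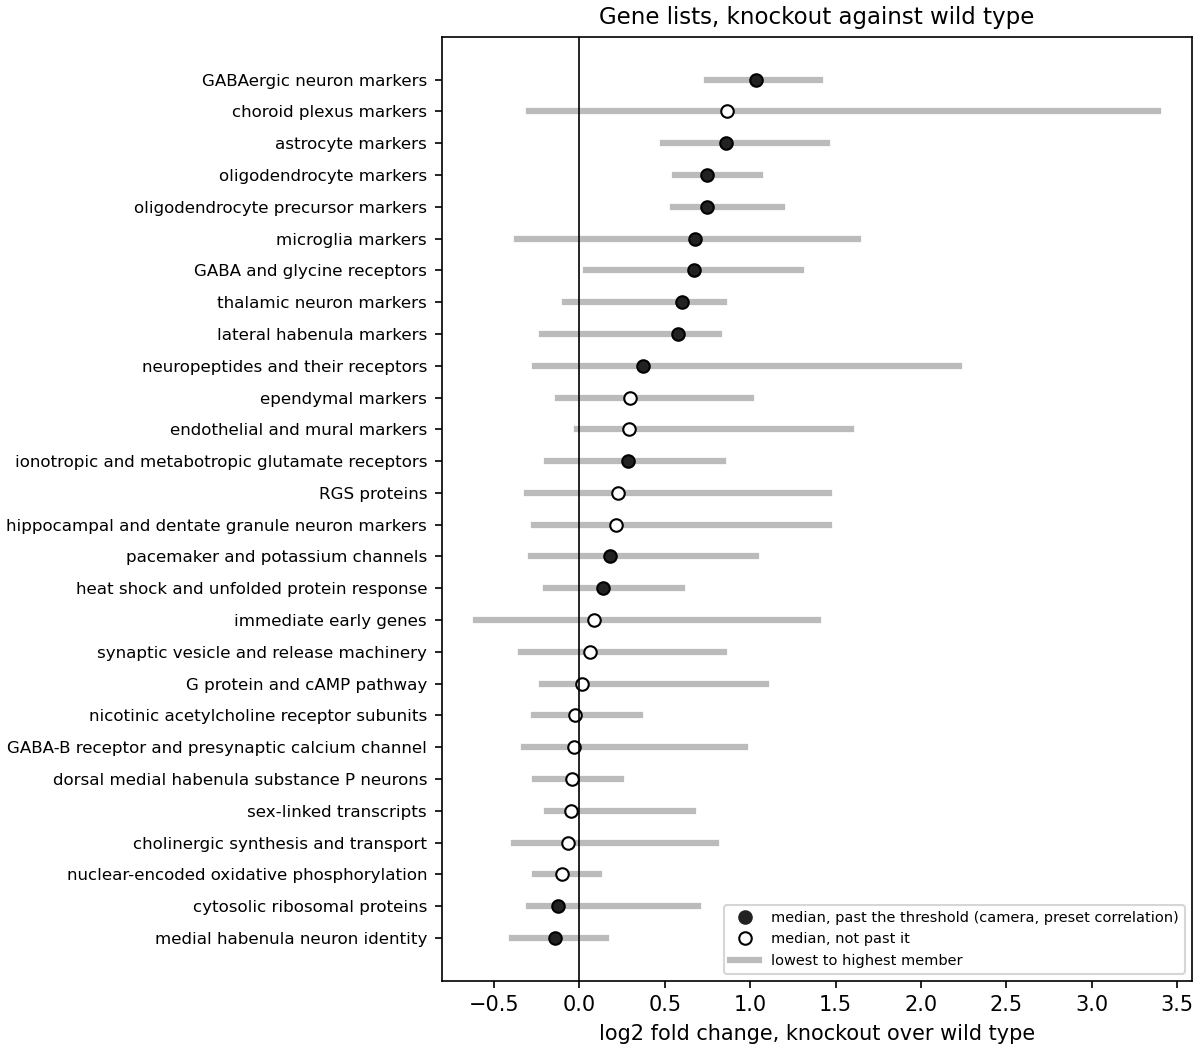
Median log2 fold change of knockout over wild type for each gene list (points), with grey lines from its lowest to its highest member; filled points are lists past the threshold in camera with a preset correlation, none of which was called with an estimated correlation. GABAergic neuron markers have a median of 1.04 and medial habenula identity genes -0.14.

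The libraries differed most by library set and by their level of non-neuronal markers. The first principal component of the 500 most variable genes held 62.8% of their variance and put all 4 earlier libraries below all 8 later ones. The mean log2 CPM of non-neuronal markers ran from 0.387 to 1.01 in the earlier libraries and from 0.746 to 3.49 in the later ones. Within the 8 later libraries, a relation chosen after the data were seen, the first component followed this score (Pearson r = -0.991, exact permutation p = 2.48e-05, the smallest 8 libraries can give; Spearman rho = -1, exact permutation p = 4.96e-05; the sign of a component is arbitrary). Without the score's own genes r was -0.989 (adjusted p = 2.48e-05 over these 2 relations by exact permutation), and without libraries 1099 and 1102 it was -0.987 (exact permutation p = 0.00417). Scores on the first component over all 12 libraries did not separate the genotypes (exact permutation p = 0.639, and 0.121 with the library set removed), nor did those of the next component (12.2% of variance, exact permutation p = 0.158). The effect of genotype was compared between the earlier and the later libraries. The edgeR interaction called 0 of 14317 genes, with 264 at an unadjusted p under 0.05, and DESeq2 called 2, Ermap and 3110001I22Rik, with 463 at an unadjusted p under 0.05. Both counts are below a share of 0.05 of the genes, which chance alone would give at that limit, so they show no excess of small p.

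Transcripts that mark medial habenula neurons were higher in the purified RNA than in the input. The acetylcholine transporter Slc18a3 had a median log2 ratio of IP over input of 3.93 (range 2.77 to 4.86 over 6 wild-type IP libraries), Slc5a7 3.52, Chat 3.20, Chrna3 3.94, Chrnb4 3.69 and Chrna5 2.23. Gpr151 was at 59.2 CPM in the input and 489 ± 103 CPM in the IP (SD, n = 6), a median log2 ratio of 2.95. Of 11309 genes, 664 were at least 2 times higher in every wild-type IP library and 1001 at most the inverse of that. Medial habenula identity genes stood at the 100th percentile of random lists (median 3.20, 14 of 17 enriched), nicotinic subunits at 99.96 (2.23, 4 of 7 enriched), cholinergic genes at 99.99 (1.39, 4 of 9 enriched and 2 depleted) and GABA-B receptor and calcium channel genes at 99.97 (1.05, 7 of 16 enriched). In the last list the calcium channel subunit Cacnb3 had 3.84 and the GABA-B auxiliary subunit Kctd8 2.90. Other enriched members included the vesicle protein Synpr (4.00), the phosphodiesterase Pde2a (3.75), the channel-interacting Kcnip1 (3.49), the transcription factor Nr4a2 (3.21) and the peptide Tac2 (3.10).

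Markers of glia and of other neurons were lower in the purified RNA. Oligodendrocyte markers had a median log2 ratio of -3.34 (13 of 16 depleted; Mobp -3.77), astrocyte markers -2.93 (11 of 16; S100b -3.76) and GABAergic markers -2.84 (5 of 6; Pvalb -4.41). Below the 2.5th percentile were also oligodendrocyte precursors (-2.68), choroid plexus (-2.45), ependymal markers (-2.40), GABA and glycine receptors (-2.39; Gabra4 -3.90), thalamic markers (-2.18; Synpo2 -3.27), lateral habenula markers (-1.75; Gap43 -3.73), neuropeptides (-1.74), glutamate receptors (-1.56; Grin2b -4.48), immediate early genes (-0.93), RGS proteins (-0.70), pacemaker and potassium channels (-0.58) and vesicle genes (0.08). Among the lists that also held enriched members were choroid plexus (2 of 7, with 3 depleted) and lateral habenula markers (2 of 9, with 1 depleted). Of 38 pacemaker and potassium channels 5 were enriched and 7 depleted, and of 59 vesicle genes 9 were enriched and 5 depleted. Vesicle genes were thus low only against their random lists, whose median was 0.33. The other lists lay between the percentile limits: microglia (-2.14), hippocampal (-0.38), endothelial (-0.18), substance P neurons (-0.13), sex-linked (-0.13), ribosomal proteins (-0.08), heat shock (0.06), G protein and cAMP genes (0.08) and oxidative phosphorylation (0.52). Of 9 microglia markers measured, 7 were depleted and 0 enriched. Their matched random lists had a median of -1.83, so the percentile could hardly show the depletion of this list.

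The single genes farthest from the input often overlap another gene, as do 57.4% of the tested genes with a position; no other way of counting such genes was tried. The 10 most enriched were Gnas (7.09), Fam219aos, Prrt2, Ilk, Rab43, Vps25, Tomm6, Galnt2, Scamp4 and Aarsd1 (5.42), and all 10 overlap another gene. The 10 most depleted were Snrpn (-7.54), Nptxr, Eno1, Gabrb1, Kcnq3, Rpl26, Fdx1l, Pter, Rims3 and Mlip (-4.91), of which 6 overlap another gene, while Eno1 and Rpl26 have near-identical copies elsewhere. Among the 4696 genes that overlap no other, a group chosen after the values were seen, 223 were enriched (4.75%) and 458 depleted (9.75%), against 6.60% and 8.40% of the 6330 that overlap another. The most enriched of these were Nfam1 (4.21), Syt15 (4.14), Chrna3 (3.94) and Tspan18 (3.90). Without TMM scaling the median of all log2 ratios moved from 0.12 to -0.07, and the enriched share of the called genes from 39.9% to 29.7%. The ratios compare the libraries at hand. An edgeR fit that pooled the spread over the IP libraries of both genotypes, and so assumed that the lone input varies like them, called 1303 transcripts higher and 1196 lower in the IP, among them 648 of the 664 enriched and 890 of the 1001 depleted.

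**Figure D4:**
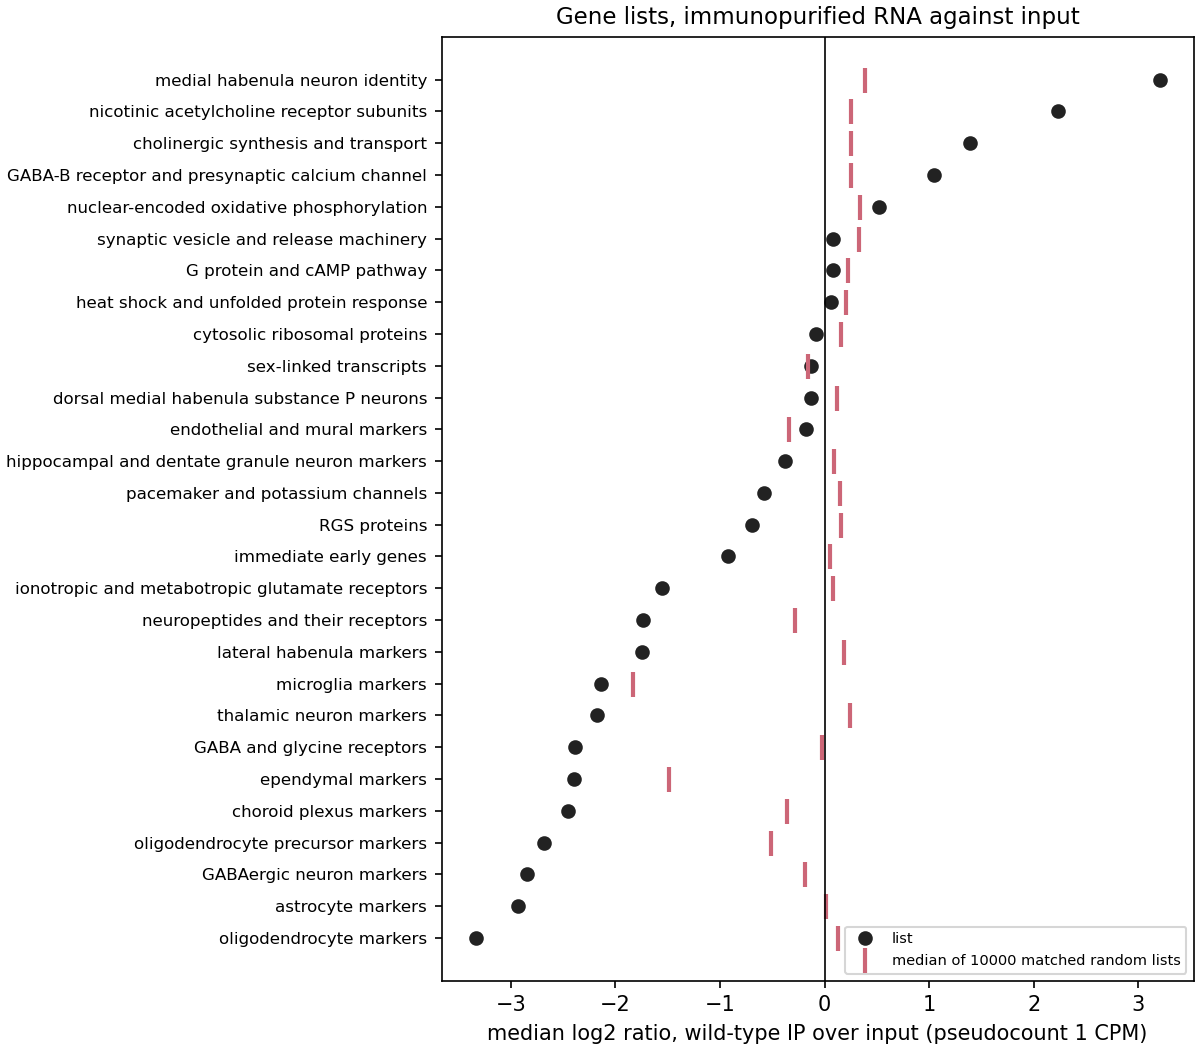
Median log2 ratio of wild-type IP over input (pseudocount 1 CPM) of each gene list (black points), with red ticks for the median of 10000 random lists matched on size and expression. Medial habenula identity genes lie highest at 3.20 and oligodendrocyte markers lowest at -3.34.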

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

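The tests of explanations below were chosen after the results they bear on had been seen.

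Within a genotype, 9 of 94 groups of 6 values had 1 library far from the others, where chance flags about 1 in 20 groups, here 4.7. Wild-type library 1091 accounted for 6: mean log2 CPM of GABA and glycine receptors (4.57, next 3.20), pacemaker and potassium channels (5.41), lateral habenula markers (5.47), ribosomal proteins (3.03, lowest) and oxidative phosphorylation genes (6.51, lowest), and the percent of alignments outside genes (13.2%). Knockout library 1099 had 16.6% of alignments outside genes. Knockout library 855 had the highest mean of cholinergic genes (5.78) and the lowest Ccdc112 (2.31 log2 CPM) among knockout libraries; library 852, of the same set, likewise had the highest mean of cholinergic genes (5.79) and the lowest Ccdc112 (3.32 log2 CPM) among wild-type libraries.

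Genes with small p cluster around Gpr151, and fewer than 5 in 100 splits matched the real one by either measure that compares neighbours with other genes. A set test of these neighbours that allows for correlation between genes did not pass (fry, p = 0.457, and p = 0.0726 for changes in either direction). At that limit the splits thus argue against chance, but fry does not. The splits do not exclude chance, since the limit of p under 0.01 was itself chosen after the values were seen. Among 100 splits of the 12 libraries 4 had as high a share relative to other genes (11.5; highest other 16.5, the 3 others with at most 2 neighbours) and 1, the real one, as small a one-sided Fisher p (4.30e-08; next 0.00211), a measure chosen after the others had been seen; among 100 that halve each library set, 1 did by share (highest other 6.48) and 1 by Fisher p (next 0.0105). As many neighbours at p under 0.01 (10) were reached by 5 splits of either kind (highest other 36 and 21), but the count alone does not test clustering, since genes elsewhere moved as well (share relative to other genes 0.96 to 2.27 in the 4 others without the restriction). The values argue against the cells that the non-neuronal score follows as the whole cause, since 12 neighbours had p under 0.01 with it as covariate. They also argue against reads shared among protocadherins as the whole cause, since the odds ratio without protocadherins was 9.07 (5 of 103 neighbours at p under 0.01). For the 5 protocadherins among the 10, leaving them out cannot test whether such reads gave their small p. Strain variants linked to the knockout allele may account for the pattern, though the allele's structure and the strain background are not given in the sources used here. Of 114 windows of 20 Mb elsewhere with at least 50 tested genes, 0 had as high a share. The highest other (5.83%) lay on chromosome 18 as well. Every knockout library carries the lost receptor and the region around it together, so an effect of the receptor's loss on these genes stays open and was not tested.

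Oxt rose in all 6 knockout pools and kept a log2 fold change of 3.96 (SE 0.44) with the non-neuronal score as covariate. This argues against the cells that the score follows as the whole cause. The score was built from non-neuronal markers, so it cannot test carry-over of other neurons. RNA carried over from hypothalamic tissue could raise Oxt. Of 16 hypothalamic markers 7 were tested besides Oxt, and 4 of the 7 lay above 0. Avp had a log2 fold change of 2.59 (SE 0.66, edgeR adjusted p = 0.969), Sim1 2.41 (SE 0.65, edgeR adjusted p = 0.999, 35 counts in wild type and 194 in knockout), Trh 1.08 and Hdc 0.74. Pomc, Agrp and Cartpt, the last the most abundant with 3404 counts in wild type and 3221 in knockout, lay at -0.16, -0.21 and -0.21. The markers were not sorted by hypothalamic nucleus, so those below 0 do not exclude carry-over from a part of the hypothalamus. The mean log2 CPM of these 7 markers gave an exact permutation p = 0.0281, and 0.0628 without Avp (by fry 0.0348 and 0.232), with 0.00649 to 0.0433 and 0.0260 to 0.128 when single libraries were left out, the lowest without Avp being without library 682 or 1094. Carry-over and a change in the neurons cannot be told apart with so few counts of Avp (20 in wild type, 129 in knockout); library 682 holds 11 of the 20, and without it the wild-type total was 9, while the log2 fold change of Avp was 3.41 (SE 0.80) without 682 and likewise without 683, since leaving out either takes this set of 1 library per genotype out of the contrast. The marker list was written after the counts of Oxt and Avp had been seen.

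For the 2 called genes together, 3 of 100 splits gave as many or more calls. Since 1 of the 2 is Gpr151, the disrupted gene, this count does not test whether Oxt arose by chance. The highest other split gave 3321 calls and points to a structure of the libraries: it puts 1091, 1099 and 1102 on 1 side, and 682 and 683 as well. Among 100 splits that halve each library set, 3 likewise gave as many, with 768 in the highest other, which again puts 1091, 1099 and 1102 on 1 side. Another of these splits puts the same libraries on 1 side, with 682, 852 and 1094, and called 0 genes.

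Of 11 marker lists of other cell types, camera with the preset correlation called 7 higher in knockout and 0 lower. With an estimated correlation, and with fry, 0 were called. Chance is not excluded, since 25 of 100 splits, and 23 of 100 that halve each library set, gave as many in 1 direction (highest other 10 in both); for all 14 called lists, of any kind and direction, it was 19 and 18 (highest other 21 in both). Less pure immunopurified RNA in some libraries may account for most of the 7: of 3 that are neither in the score nor GABAergic markers, 0 stayed past the threshold with the non-neuronal score as covariate, and their medians moved from 0.75 to -0.03 (oligodendrocyte precursors, of whose 9 members 3 are in the score), from 0.60 to 0.03 (thalamic) and from 0.58 to 0.05 (lateral habenula). For GABAergic markers the values argue against the cells that the score follows as the whole cause. With the covariate their median stayed at 0.71 with all 8 members above 0 (limma's camera with an estimated correlation, unadjusted p = 0.00579). Unlike the camera adjusted p of 0.393 without the covariate, this p was not adjusted over the 28 lists, and the list was chosen after its results were seen. The difference per library was 0.70 with the covariate against 1.11 without it (exact permutation within library sets, p = 0.0214 for both). Without the covariate and with the sets ignored, the exact permutation p was 0.0693. The score was built from non-neuronal markers, so it cannot test carry-over of GABAergic neurons into the immunopurified RNA, which stays open. Which GABAergic cells these would be was not tested, and a biological difference between genotypes stays open for these markers as well.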

How the results depend on the processing

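The alternative without the 3 libraries of highest non-neuronal score, the count of neighbours at p under 0.01 and the group of genes overlapping no other gene were chosen after the data were seen. For the 2 genes past the threshold, later libraries only gave 1, earlier libraries only 1, a filter of 1 CPM in 6 libraries 1 and DESeq2 12; the other settings gave 2, as did leaving out any library. DESeq2 gave no adjusted p for 278 genes. The Gpr151 log2 fold change was -1.54 in the later libraries only, past the threshold in all other settings, and -1.75 to -1.53 without 1 library. Genes near Gpr151 past the threshold were 1, but 0 with later libraries only and 5 with DESeq2. Neighbours at p under 0.01 were 10, but 5 with later libraries only, 6 within 5 Mb, and 6 without WT_IP replicate 1 (library 682) or without KO_IP replicate 1 (library 683). Leaving out single libraries gave 6 to 11. The odds ratio of neighbours at p under 0.01 was 12.2, but 5.89 with earlier libraries only, 7.43 with DESeq2 and 19.3 with a filter of 1 CPM in 6 libraries, and 3.94 (without library 1091) to 20.3 (without library 852) when single libraries were left out. Lists past the threshold were 14, but 3 with earlier libraries only, 1 with the non-neuronal score as covariate, 9 without the 3 libraries of highest score, and 0 with an estimated correlation, with fry and with fry in either direction. The interaction called 0 genes and 2 with DESeq2. Enriched transcripts were 664, but 1528 with library 852 only, 1303 with edgeR and a spread pooled over IP libraries, and 223 among genes overlapping no other gene; depleted transcripts were 1001, but 507 with all 12 IP libraries, 2119 with library 852 only and 458 among genes overlapping no other gene. Without 1 wild-type library they ranged from 644 to 799 and from 1006 to 1485, the highest without library 1091. Fewer libraries or genes entered several of these by construction; for the others the cause was not tested.

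Among 69 named genes and 1774 comparisons with alternatives, 1736 kept direction and side of the threshold and 29 reversed, none of them in a gene past the threshold. With the non-neuronal score as covariate the log2 fold change was 0.0642 for Slc18a3, 0.17 for Slc5a7, 0.15 for Chrna3, 0.12 for Chrnb4, -0.0814 for Abcc9, 0.00194 for Cox7c and -0.12 for Xist. With earlier libraries only it was 0.0646 for Chrna3, 0.0265 for Chrnb4, 0.0526 for Slc17a7, 0.0376 for Cox7c, -0.13 for Mobp, 0.00664 for Syt6 and -0.0556 for Rgs16, and with later libraries only 0.00534 for Slc5a7. Without the 3 libraries of highest score it was 0.10 for Slc5a7, 0.13 for Chrna3, 0.0489 for Chrnb4 and -0.25 for Xist. Without 1 library Slc5a7 ranged from -0.22 to 0.14, Chrna3 from -0.16 to 0.0653 and Chrnb4 from -0.26 to 0.0193, the highest each without library 1092 and the lowest without library 1100. The cause was not tested. Depth limits genes such as Oxt, which had at most 3 counts per wild-type library.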

Other observations

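Symbols listed in only 1 annotation were tested apart. Of 160 tested symbols found only in the later IP libraries, edgeR called 0, with 3 at an unadjusted p under 0.05; of 979 found only in the earlier ones it called 0, with 50 at an unadjusted p under 0.05.

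Transcripts of the Y chromosome were present in both genotypes. Ddx3y was at 40.3 ± 15.9 CPM in wild type and 40.5 ± 20.8 CPM in knockout, and the X-linked Xist at 2.66 ± 1.78 and 4.34 ± 4.60 CPM (SD, n = 6 each).

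Some markers listed for other regions were themselves enriched by the purification. Neurod2, listed for hippocampal neurons, had a median log2 ratio of 3.78 and Sostdc1, listed for choroid plexus, 3.06.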
